A study of Mus musculus with 11 samples.

How the data were processed

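Messenger RNA levels were measured in 11 libraries of CD4 T cells. Per the labels' protocols, spleens of Ldlr-/- mice were meshed and freed of erythrocytes, CD4 T cells were taken out with CD4 microbeads, and the cells were activated with anti-CD3/CD28 beads in medium with IL-2 at 20 ng/ml. LDL or VLDL was added at 5 µg/ml, and beads and medium were removed after 72 h. Per the labels' protocols, RNA was isolated with a column kit with DNase treatment and libraries were made with the KAPA mRNA Hyperprep kit.

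The authors deposited a table of raw counts, with 1 row per RefSeq transcript and 1 column per library. Per the submitters' processing notes, CASAVA 1.8.2 and the aligner STAR 2.5.2b were used and the genome build was mm10. The counting tool, its use of strand and any read filter are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated. The table held 42361 transcripts, 36085 with the NM prefix of protein-coding transcripts and 6276 with the NR prefix of noncoding ones. The deposited counts of transcripts of the same gene were nearly equal. Among 4425 genes with several transcripts and a mean count of at least 100, the lowest transcript held a median of 97.4% of the count of the highest, so reads in shared exons were counted for each transcript and summing them would count reads repeatedly.

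Transcript accessions were matched to gene symbols with the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, for 42203 transcripts and with GENCODE M21 for a further 65. The remaining 93, with 0.259% of the counts, kept their accession as name. For each gene the transcript with the highest mean count was kept, which gave 25160 genes, of which 8193 had more than 1 transcript. Summing the transcripts of a gene and testing each transcript separately were tried as alternatives. Coordinates are 1-based positions of genes in the RefSeq annotation of that assembly.

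Libraries were grouped by the title and stimulus given in the labels. Each pair of libraries of 1 group differed by more than counting noise, with a chi-square per degree of freedom between 3.41 and 12.35, which repeat sequencing of 1 library would not give. Library preparation alone can give it, so it does not show separate animals or cultures, and each library was counted as a replicate as labelled. Total gene counts per library ran from 8382019 to 19890600. The 10 most abundant genes took 4.61% to 5.31% of a library's counts.

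The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on the counts, with TMM scaling (factors 0.99 to 1.02), the filterByExpr filter by group and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The 11 libraries entered 1 fit with 1 coefficient per group, 8 residual degrees of freedom and no covariate. 11991 genes passed the filter. The common dispersion was 0.0065, a biological coefficient of variation of 8.06%. Log2 fold changes are given with their standard error (SE). CPM values, counts relative to the TMM-scaled library total, are given as mean and SD over libraries, and log2 CPM used a prior count of 2.

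Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, for lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were run beside it. Of 47 lists, 37 for functions and 10 for other cell types of the spleen, 44 had enough members; 1108 of 1133 memberships were matched to a gene in the table. Counts of called members are given after adjustment over the 11991 genes and, for part of the lists, also adjusted over the list alone.

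The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. Named genes are, per comparison, the 10 with the largest rise and the 10 with the largest fall among genes with an adjusted p under 0.05, a mean log2 CPM of at least 2 and no overlap between the groups' libraries. Gene models without a name, pseudogenes and antigen receptor segments were passed over. Where nothing passed, the smallest p-values took their place. For a list that passed camera up to 4 members with the smallest p in its direction were named, and for other lists up to 2. A fixed set of genes of interferon signalling, helper T cell types, lipid handling and identity was named whatever its values.

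Replicate numbers were compared across groups through the correlation, over tested genes, of each library's deviations from its group mean. Numbers were to be treated as pairs if every same-numbered pair lay above 0.1. Over all groups the lowest was 0.0645, so the rule was not met. Same-numbered LDL and Ctrl libraries correlated at 0.129 to 0.485 in 4 pairs, each above that limit. For this comparison the fit with the number as a block is therefore given beside the result where it changes it. Applying the limit to a single comparison was not part of the rule. The pairing comes from the data; the labels do not say what a number marks.

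Alternatives were DESeq2's size factors, upper-quartile scaling, library size alone, other low-count filters, DESeq2 1.42.0, limma-voom with sample quality weights, fits of the compared groups alone, the replicate number as a block and leaving out each library in turn. Further alternatives were chosen after the data were seen: both treatments of transcripts named above, libraries with the numbers 1, 3 and 4 alone, a correction for GC content and transcript length, that correction with the block, a B cell score as covariate, and counts thinned to the smallest library.

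The procedure was tested on simulated data, 5 data sets per comparison, each with 200 changed genes among 11991 and no shared effect of the replicate number. For VLDL against Ctrl it recovered 35.5% of genes changed 1.25-fold, 68.4% of those changed 1.5-fold and 86.4% of those changed 2-fold, with 5.38% of calls false. For LDL against Ctrl the shares were 40%, 71.6% and 83.9%, with 7.07% false. For VLDL against LDL they were 36.4%, 64.5% and 86.4%, with 6.39% false. Changes below 1.25-fold are therefore often missed at this depth and number of libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact permutation tests and plots.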

Results

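The data were RNA sequencing counts of 11 libraries of splenic CD4 T cells from Ldlr-/- mice. These mice lack a functional low-density lipoprotein receptor and are used as a model of hyperlipidemia. The cells were activated in culture for 72 h with beads that engage CD3 and CD28 and with IL-2, which drive T cells to divide. 4 libraries came from cultures without added lipoprotein (Ctrl), 4 from cultures with LDL, the cholesterol-rich low-density lipoprotein, and 3 from cultures with VLDL, the triglyceride-rich very-low-density lipoprotein, each at 5 µg/ml. Per the labels, LDL and VLDL came from different suppliers, so the comparison of both also compares these preparations. Libraries are named by their group and the number in their label; the VLDL libraries carry the numbers 1, 3 and 4. The Ctrl libraries 1 to 4 held 8382019, 11313733, 10164275 and 13070056 gene counts, the LDL libraries 1 to 4 held 8778565, 16223441, 12911209 and 16687842, and the VLDL libraries 1, 3 and 4 held 19890600, 13836924 and 12255005. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

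Cd4 was counted at 418 ± 11.3 CPM (SD, n = 4) in Ctrl, 421 ± 11.6 CPM (n = 4) with LDL and 471 ± 7.9 CPM (n = 3) with VLDL. Cd8a, a marker of CD8 T cells, stood at 6.51 ± 1.52, 6.53 ± 3.54 and 12 ± 4.59 CPM in the same order. With VLDL, Cd4 was higher by 0.17 ± 0.04 against Ctrl (edgeR adjusted p = 0.0155) and by 0.16 ± 0.04 against LDL (0.0321). The first call was lost without VLDL 4 (0.0595), the second without any library other than LDL 4 (up to 0.104). Cd8a was at 0.92 ± 0.37 (0.133) and 0.96 ± 0.36 (0.15) without passing. The CD8 T cell list, with 2 matched genes, was too short to be tested. Ldlr transcript was counted in every library, at 427 ± 52 CPM in Ctrl, 468 ± 27.9 CPM with LDL and 475 ± 19.4 CPM with VLDL. It checks no group label, since every library is labelled Ldlr-/- and counts over a disrupted gene can come from its remaining exons. In a principal component analysis the VLDL libraries lay apart from the others on the first component (21.9% of the variance), and the libraries numbered 2, Ctrl 2 and LDL 2, lay apart on the second (16.8%).

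The first comparison asked how VLDL changed gene expression of the activated cells, the lipoprotein that the series title puts at the centre. With VLDL (n = 3) against Ctrl (n = 4), genes induced by interferon-gamma rose: 20 of 36 measured members were called higher and 0 lower. Genes of MYC targets and ribosome biogenesis fell, with 21 of 30 members lower, as did genes of cholesterol synthesis, with 15 of 25 lower, and of fatty acid synthesis and desaturation, with 11 of 20 lower. The changes were small in size: the called genes had a median absolute log2 fold change of 0.33, and 15 of the higher and 63 of the lower ones passed a 2-fold change. The edgeR quasi-likelihood test called 1130 of 11991 genes, 530 higher (46.9%) and 600 lower. With upper-quartile scaling 660 were higher (56.6%) and 506 lower, so which direction held more genes depends on the scaling. In 1089 of the 1130 the libraries of both groups did not overlap; among all tested genes 22% did not overlap, where chance gives 5.71%. Leaving out Ctrl 3 gave 609 called genes, leaving out Ctrl 4 gave 658, leaving out VLDL 3 gave 440 and leaving out VLDL 4 gave 476.

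**Figure D1:**
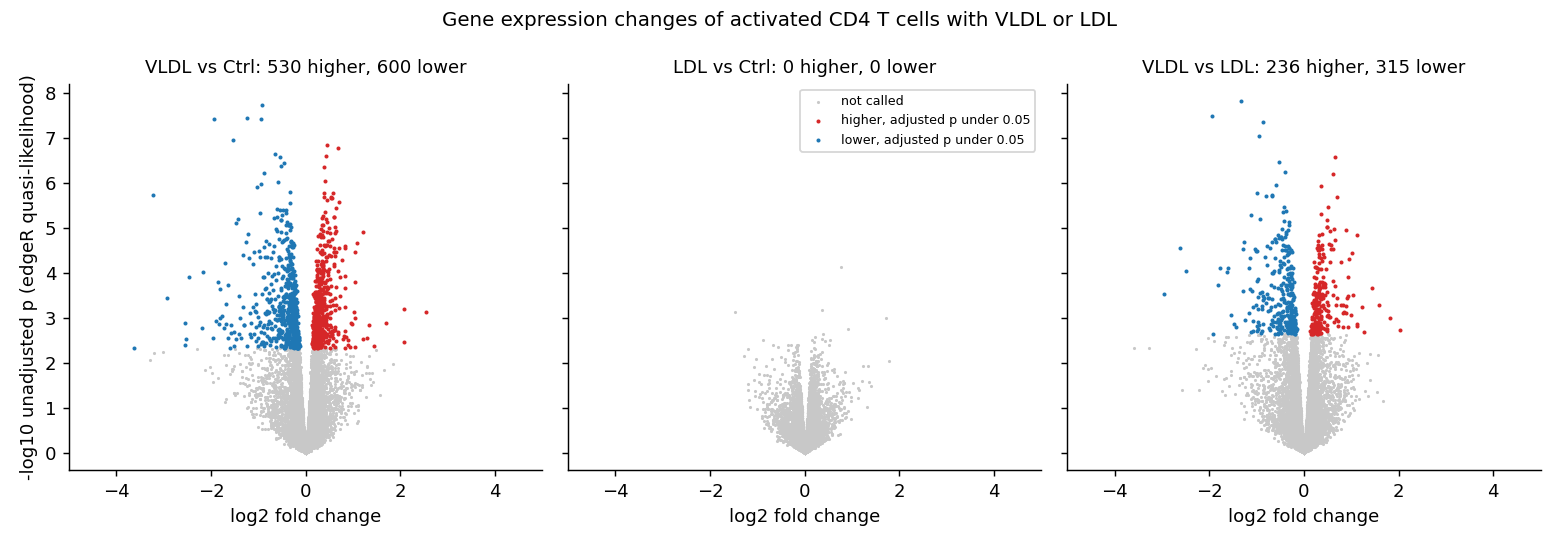
Log2 fold change (x axis) against the negative log10 of the unadjusted edgeR quasi-likelihood p (y axis) for 11991 genes in each comparison, with genes called higher in red and lower in blue. VLDL against Ctrl has 530 higher and 600 lower genes, LDL against Ctrl has 0, and VLDL against LDL has 236 higher and 315 lower.

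Among the interferon-gamma-induced genes, Tap1 and Tapbp, which load peptides onto MHC class I, rose by 0.39 ± 0.05 and 0.37 ± 0.06 on the log2 scale (± SE; adjusted p = 0.000965 and 0.0021, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Psmb9, an immunoproteasome subunit, rose by 0.41 ± 0.06 (adjusted p = 0.0015), and Socs1, which restrains JAK-STAT signalling, by 0.36 ± 0.05 (adjusted p = 0.0018). In the GRCm38.p6 assembly Tap1 lies at chromosome 17, 34187556 to 34197225, and Psmb9 beside it at 34182030 to 34187330. The list's median log2 fold change was 0.25. Adjusted over the list alone, 26 members were higher. Camera gave the list an adjusted p of 6.07e-20, and adjusted p = 0.0879 with an estimated correlation; fry gave 0.00382. The list of antigen presentation genes had 13 of 27 members higher, 18 adjusted over the list alone. It shares Tap1, Tap2, Tapbp, Psmb8, Psmb9, Psmb10, Nlrc5, Ciita and B2m with the interferon-gamma-induced list, so the results of both lists partly repeat each other. H2-Q4, an MHC class I gene whose reads near-identical family members could share, rose by 0.38 ± 0.06 (adjusted p = 0.00286), and Cd74, the invariant chain of MHC class II, was at 0.51 ± 0.17 without passing (adjusted p = 0.0714). Camera gave 5.72e-14, and adjusted p = 0.0879 with an estimated correlation. Without VLDL 4, 8 members of this list were called. In this comparison 1130 of 11991 genes were called, and 3056 had an unadjusted p under 0.05. Markers of B cells and plasma cells, which carry much MHC class II, had a median log2 fold change of 0.37 with 0 of 14 members called. 4 were called without Ctrl 1 and 1 without VLDL 3. Their camera adjusted p was 0.021, and adjusted p = 0.641 with an estimated correlation; camera no longer passed without Ctrl 3 (0.108), Ctrl 4 (0.0588) or VLDL 1 (0.427). Markers of conventional dendritic cells, which also present antigen, had a median of 0.39 with 0 of 10 members called, 2 adjusted over the list alone and 3 without Ctrl 1. That list shares the MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 with the antigen presentation list, so it gives no separate sign of dendritic cells. Camera gave the conventional dendritic cell list 0.0319, and adjusted p = 0.39 with an estimated correlation; it did not pass without Ctrl 3 (0.0532), Ctrl 4 (0.0526), VLDL 1 (0.103) or VLDL 4 (0.0579), and stood at 0.05 without Ctrl 2.

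Of the type I interferon-stimulated genes, 15 of 48 were higher, 19 adjusted over the list alone, and 33 did not pass. Zbp1, a sensor of Z-form nucleic acid, rose by 0.58 ± 0.07 (edgeR adjusted p = 0.000965), from 140 ± 15.5 CPM in Ctrl to 209 ± 17.1 CPM. Stat2, part of the transcription factor that type I interferons activate, rose by 0.31 ± 0.07 (adjusted p = 0.0108) and by 0.20 without VLDL 4. Ifi35 rose by 0.36 ± 0.07 (adjusted p = 0.00762). The antiviral gene Ifit3 rose by 0.80 ± 0.22 (adjusted p = 0.0381), and Stat1, which both interferon types activate, by 0.31 ± 0.08 (adjusted p = 0.0301). The call of Ifit3 was lost without Ctrl 1, Ctrl 3, Ctrl 4, VLDL 3 or VLDL 4 (adjusted p up to 0.178), and that of Stat1 without any library other than Ctrl 1 (up to 0.11). Irf7 was at 0.68 ± 0.25 (adjusted p = 0.0982), Isg15 at 0.41 ± 0.34 (0.48) and Ifit1 at 0.39 ± 0.24 (0.345); these did not pass. The list's mean was 0.27 with all libraries and 0.06 without VLDL 4, which carried the highest value of the list's mean of the 11 libraries. Camera gave 5.84e-08, and adjusted p = 0.497 with an estimated correlation; fry gave 0.132. The number of members called was 7 without Ctrl 1, 8 without Ctrl 2, 5 without Ctrl 3, 3 without Ctrl 4, 5 without VLDL 3 and 3 without VLDL 4.

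Of 8 measured interferon genes and receptors, 3 rose: the kinase gene Jak2 by 0.42 ± 0.07 (edgeR adjusted p = 0.00415), the receptor subunit Ifnar1 by 0.23 ± 0.05 (0.0158) and the kinase gene Tyk2 by 0.22 ± 0.06 (0.0257). Camera gave 0.000544, and adjusted p = 0.0879 with an estimated correlation; without VLDL 1, 1 member was called. Ifnar1 was also lost without Ctrl 3 or VLDL 3 (adjusted p up to 0.0741) and Tyk2 without Ctrl 4 or VLDL 4 (up to 0.112). Ifng, which encodes interferon-gamma, was at -0.18 ± 0.55 (adjusted p = 0.884). Its counts were 5.44 ± 4.18 CPM in Ctrl, 5.35 ± 4.53 CPM with LDL and 4.93 ± 1.27 CPM with VLDL, with 11.7 CPM in Ctrl 2 and 12.1 CPM in LDL 2; no VLDL library carries the number 2. Without Ctrl 2 its log2 fold change was 0.53 (adjusted p = 0.579), and among libraries numbered 1, 3 and 4 it was also 0.53 (adjusted p = 0.203). With the replicate number as a block it was 0.58 and passed (edgeR adjusted p = 0.0461), so direction and call of Ifng depend on the fit.

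**Figure D2:**
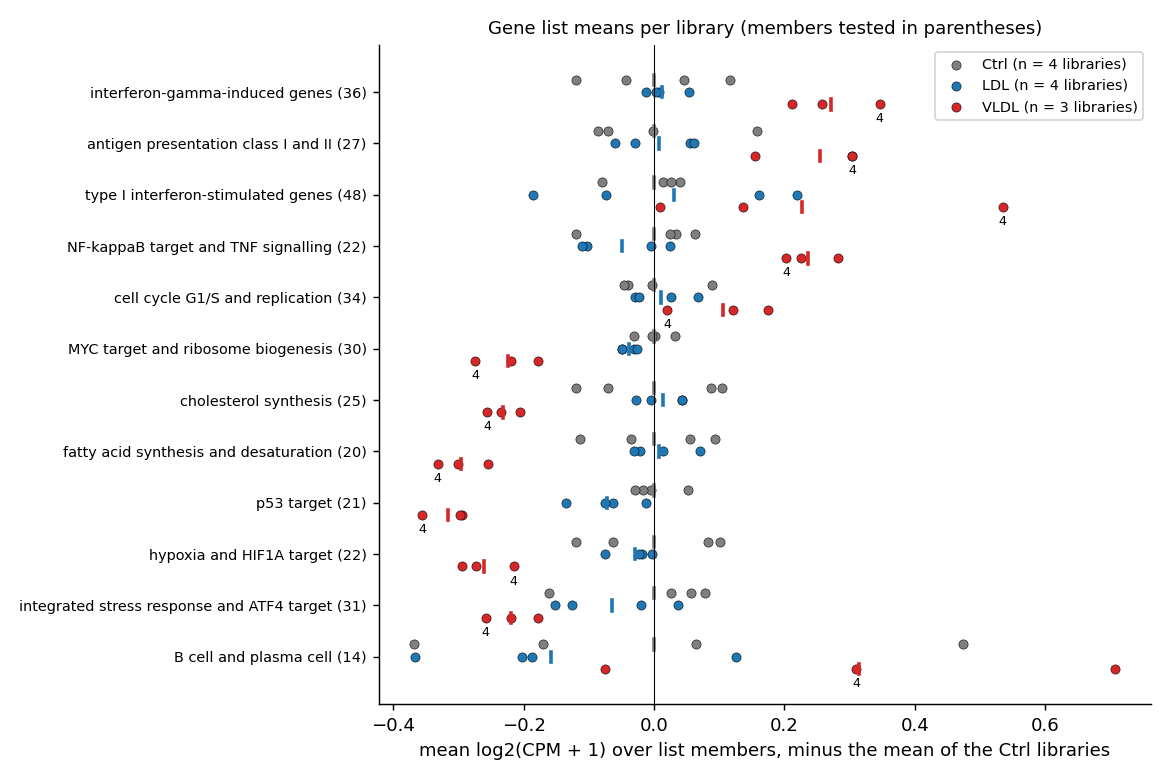
Mean log2(CPM + 1) over the tested members of 12 gene lists in each library, minus the mean of the Ctrl libraries (x axis), for Ctrl (grey, n = 4), LDL (blue, n = 4) and VLDL (red, n = 3); vertical bars are group means and the digit 4 marks VLDL 4. The 3 VLDL libraries lie to the right of every Ctrl and LDL library for the interferon-gamma-induced list, and VLDL 4 lies farthest to the right for the type I list.

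Genes of lipid synthesis fell with VLDL. Hmgcs1, which makes the precursor HMG-CoA, fell by 0.51 (SE 0.07, edgeR adjusted p = 0.00161), from 1099 ± 114 CPM in Ctrl to 772 ± 33.8 CPM. Hmgcr, the rate-limiting enzyme of cholesterol synthesis, fell by 0.36 (SE 0.06, adjusted p = 0.00372), Sqle, squalene epoxidase, by 0.34 (SE 0.05, 0.0021) and Fdft1, squalene synthase, by 0.36 (SE 0.06, 0.00372). Adjusted over the list alone, 18 of 25 members of the cholesterol synthesis list were lower. Camera gave 1.69e-14, adjusted p = 0.195 with an estimated correlation, and fry 0.0126; without VLDL 4, 9 members were called. Of the fatty acid genes, Scd1, which desaturates stearate, fell by 0.88 (SE 0.10, adjusted p = 0.000512), Fasn, fatty acid synthase, by 0.59 (SE 0.07, 0.000718) and Scd2 by 0.41 (SE 0.06, 0.0021). On the list alone 12 of 20 were lower, camera gave 1.05e-10, and adjusted p = 0.0814 with an estimated correlation. The number called was 6 without Ctrl 3, 6 without Ctrl 4, 7 without VLDL 1, 6 without VLDL 3 and 7 without VLDL 4. Cpt1a, which carries long-chain fatty acids into mitochondrial oxidation, rose by 0.43 ± 0.07 (adjusted p = 0.00286) and was the 1 called member of 24 on the fatty acid oxidation list (camera 0.639).

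Of genes for lipoprotein receptors and lipid handling, 4 of 26 fell and 1 rose. Lrp12 fell by 0.61 (SE 0.09, edgeR adjusted p = 0.0021), the scavenging receptor gene Lrp1 by 1.27 (SE 0.20, 0.00268), Soat1, which esterifies cholesterol for storage, by 0.49 (SE 0.08, 0.00268) and the HDL receptor gene Scarb1 by 0.34 (SE 0.07, 0.00668). Camera gave the lipoprotein receptors and lipid handling list 0.0372, and adjusted p = 0.18 with an estimated correlation; camera did not pass without Ctrl 2 (0.054), Ctrl 3 (0.0513) or VLDL 4 (0.0555). Ldlr was at 0.15 ± 0.08 (adjusted p = 0.23) and Vldlr at -0.31 ± 0.18 (0.306). The targets of the sterol-sensing receptor LXR had 1 of 11 members called and a camera adjusted p of 0.764; its exporters Abca1 and Abcg1 were at 0.51 ± 0.28 (0.276) and -0.19 ± 0.15 (0.47). The called member, Nr1h2, is itself an LXR gene on that list, and its call was lost without any library other than VLDL 1 (adjusted p up to 0.16).

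Lists of MYC, p53 and integrated stress response targets fell as well. Myc, the transcription factor that drives ribosome production, fell by 0.43 (SE 0.08, edgeR adjusted p = 0.00539), the nucleolar gene Gnl3 by 0.35 (SE 0.05, 0.0018) and Mybbp1a by 0.27 (SE 0.04, 0.00272). Adjusted over the list alone, 23 of the 30 members of the MYC and ribosome biogenesis list were lower, and camera gave 1.66e-18, and adjusted p = 0.0299 with an estimated correlation. Without VLDL 3 and without VLDL 4, 11 members were called in each case. Of 57 cytosolic ribosomal protein genes 0 were called, 0 also adjusted over the list alone, and camera gave 0.0942. Targets of p53 fell in 10 of 21 cases, 13 on the list alone, with Cdkn1a, the cell cycle inhibitor p21, at -0.94 ± 0.09 (adjusted p = 0.000113) and Ccng1 at -0.42 ± 0.06 (0.0018); camera gave 9.96e-10, and adjusted p = 0.022 with an estimated correlation. Without VLDL 3, 4 members were called and without VLDL 4, 3. Genes of the integrated stress response fell in 10 of 31 cases, 15 on the list alone, among them its transcription factor Atf4 by 0.36 (SE 0.06, 0.00287) and the serine synthesis gene Psat1 by 0.32 (SE 0.06, 0.00457). Camera gave 3.94e-08, and adjusted p = 0.18 with an estimated correlation; without VLDL 4, 6 members were called.

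Hypoxia and HIF1A targets fell in 9 of 22 cases, 11 on the list alone, among them the oxygen sensor Egln3 at -0.54 ± 0.08 (edgeR adjusted p = 0.0014) and Mxi1, a MYC antagonist, at -0.63 ± 0.09 (0.00199). Camera gave 1.78e-08, and adjusted p = 0.168 with an estimated correlation. On the glycolysis list 5 of 24 fell and 1 rose, with Hk2, which traps glucose in the cell, at -0.65 ± 0.07 (0.000318) and the lactate transporter Slc16a1 at -0.46 ± 0.05 (0.000385). The median of that list was 0.01, its mean -0.06, and camera did not pass (0.0915). Genes of G1/S and replication rose in 4 of 34 cases, 11 on the list alone, led by the thymidine kinase Tk1 at 0.29 ± 0.06 (0.00902); camera gave 2.36e-05, and adjusted p = 0.584 with an estimated correlation. The number called was 9 without Ctrl 1, 2 without Ctrl 4, 2 without VLDL 1, 1 without VLDL 3 and 8 without VLDL 4. Genes of G2/M and mitosis rose in 5 of 34 cases and camera did not pass (0.119); the number was 1 without Ctrl 2, 3 without Ctrl 3, 2 without Ctrl 4, 1 without VLDL 3 and 0 without VLDL 4. Of the heat shock genes 3 of 15 fell, with the mitochondrial chaperone Hspd1 at -0.35 ± 0.06 (0.00348), camera 0.021, adjusted p = 0.488 with an estimated correlation; the heat shock response list did not pass camera without VLDL 4 (0.201).

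Genes of T cell state moved in parts. Of the naive and central memory list 6 of 22 rose and 1 fell, 8 and 1 on the list alone. Sell, the lymph node homing receptor, rose by 0.44 ± 0.06 (edgeR adjusted p = 0.00165), Actn1 by 0.52 ± 0.09 (0.00372) and Als2cl by 0.55 ± 0.07 (0.000999). Camera gave 2.36e-05, and adjusted p = 0.317 with an estimated correlation; without Ctrl 3, 3 members were called higher. NF-kB targets rose in 7 of 22 cases, 13 on the list alone, with the NF-kB subunits Relb at 0.62 ± 0.10 (0.0021) and Nfkb2 at 0.32 ± 0.06 (0.00779). Camera gave 1.46e-07, and adjusted p = 0.0814 with an estimated correlation; 4 members were called without Ctrl 3, 4 without Ctrl 4 and 3 without VLDL 4. Of the Th1 genes 3 of 22 fell and camera did not pass (0.173): Eomes fell by 1.19 (SE 0.21, 0.00375), Ly6c2 by 0.97 (SE 0.24, 0.0236) and the chemokine receptor Ccr5 by 1.30 (SE 0.33, 0.0257), with 1 called without VLDL 3 and 1 without VLDL 4. The call of Ly6c2 was lost without Ctrl 3, VLDL 3 or VLDL 4 (adjusted p up to 0.089) and that of Ccr5 without Ctrl 2 or any VLDL library (up to 0.0856). Tbx21, the Th1 master regulator, was at 0.63 ± 0.36 (0.297) and Cxcr3 at -0.13 ± 0.31 (0.847). The NK cell and ILC list, which holds Eomes and Gzma, had 1 of 3 members lower, Eomes, and a median of -1.19. Camera gave it 0.0424, adjusted p = 0.195 with an estimated correlation, and fry 0.045; camera did not pass without Ctrl 2 (0.0865), Ctrl 3 (0.0562), VLDL 1 (0.113) or VLDL 4 (0.0579).

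Of the Th2 genes 2 of 17 fell, Plac8 by 1.07 (SE 0.23, edgeR adjusted p = 0.0108) and the cytokine Il5 by 1.82 (SE 0.44, 0.021), while Gata3, the Th2 master regulator, was at -0.06 ± 0.16 (0.865). Il5 counts were very low, at 1.07 to 2.3 CPM in the Ctrl libraries and 0.289 to 0.603 CPM in the VLDL libraries. Camera gave the Th2 list 0.0424, and adjusted p = 0.663 with an estimated correlation; the Th2 call was lost without Ctrl 2 (0.175), Ctrl 3 (0.0761), Ctrl 4 (0.0653) or VLDL 1 (0.457), and 1 member was called without Ctrl 2, 0 without VLDL 3 and 1 without VLDL 4. The call of Plac8 was lost without VLDL 3 (0.0529) and that of Il5 without Ctrl 2, VLDL 3 or VLDL 4 (up to 0.0881). Regulatory T cell genes went both ways, 2 higher and 1 lower of 21, 5 and 5 on the list alone (camera 0.764). Among them the costimulatory receptor Tnfrsf18 rose by 0.33 ± 0.06 (0.00343), Ikzf2 fell by 0.82 (SE 0.14, 0.00372), and Foxp3, the master regulator of these cells, was at -0.65 ± 0.22 without passing (0.0738); it passed without VLDL 4 (-0.92, 0.031), among libraries numbered 1, 3 and 4 (-0.72, 0.0119) and with no low count filter (-0.64, 0.0325). Without VLDL 3, 1 member of that list was called higher. The cytotoxic list had 0 of 15 members called (camera 0.492): Gzma was at -1.22 ± 0.69 (0.294) and Gzmb at -0.79 ± 0.30 (0.111), with Gzma at 107 CPM in Ctrl 2 and 95.8 CPM in LDL 2, against 13.1 to 39.7 CPM in the other Ctrl and LDL libraries. Of the Th17 genes 0 of 11 were called (camera 0.492), and Rorc was too low to be tested. Of the T follicular helper genes 1 of 13 was called (camera 0.599), with Bcl6 at 0.29 ± 0.21 (0.431); that 1 call was lost without Ctrl 3, Ctrl 4, VLDL 1, VLDL 3 or VLDL 4.

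**Figure D3:**
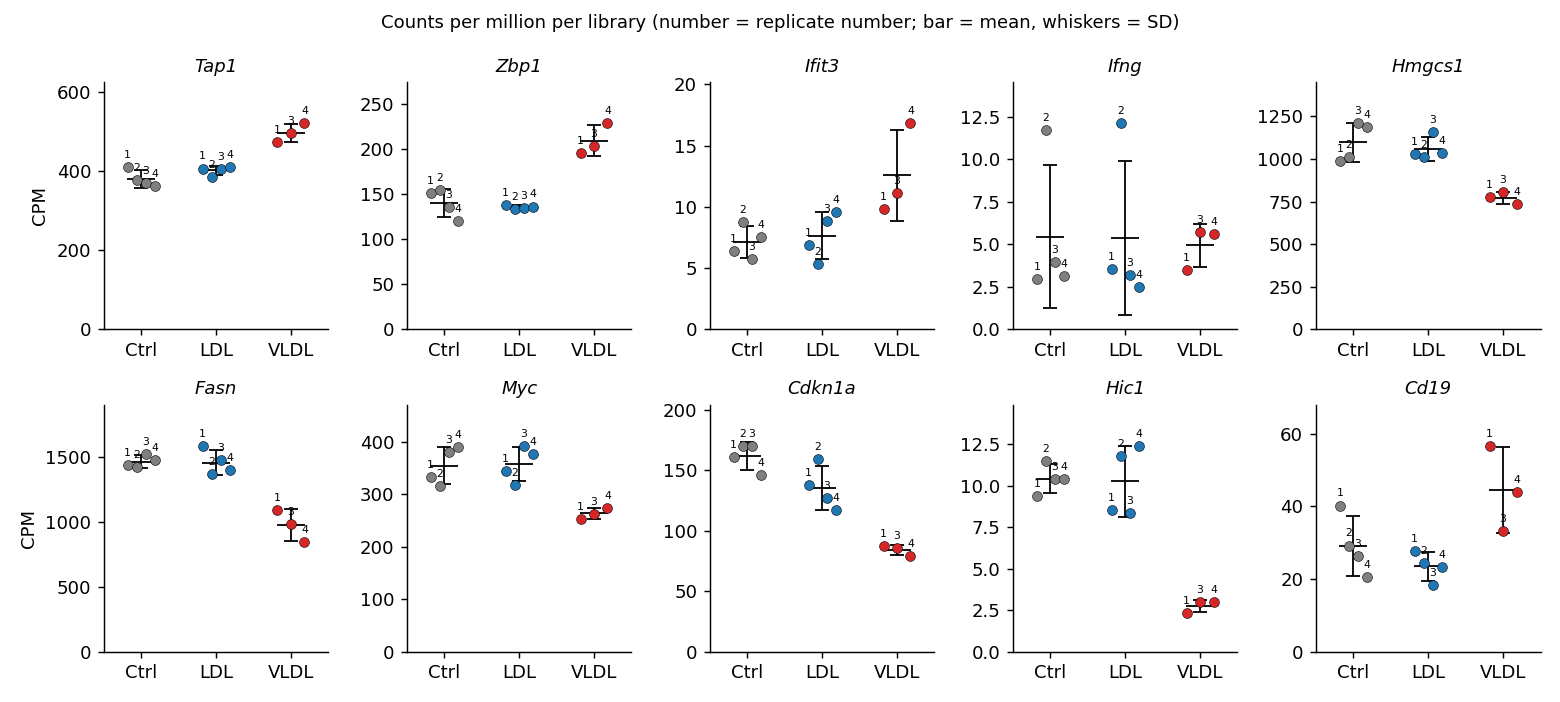
CPM of 10 genes (y axis, from 0) in each library of Ctrl (n = 4), LDL (n = 4) and VLDL (n = 3); digits are the replicate numbers, horizontal bars the group means and whiskers the SD. Tap1 runs from 362 to 412 CPM in Ctrl and from 474 to 521 CPM with VLDL, and Ifng reaches 11.7 and 12.1 CPM in the libraries numbered 2.

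Among genes with a mean log2 CPM of at least 2 and no overlap between the libraries, the largest falls were in Hic1, a transcriptional repressor, at -1.94 ± 0.18 (edgeR adjusted p = 0.000113), from 10.4 ± 0.869 CPM in Ctrl to 2.75 ± 0.38 CPM, Gcnt2 at -1.64 ± 0.33 (0.00832), Prr5l at -1.53 ± 0.16 (0.000269), Emilin2 at -1.46 ± 0.22 (0.00179) and Selenbp1 at -1.42 ± 0.21 (0.00165). Hic1 lies at chromosome 11, 75161377 to 75170255. Nav2, Car5b, Ahnak, Ccr5 and Lrp1 followed, between -1.41 and -1.27. Ahnak was at 397 CPM in Ctrl 2 and 155 to 176 CPM in the other Ctrl libraries; its log2 fold change was -1.30 with all libraries and -0.86 without Ctrl 2, and its call was lost without VLDL 1, VLDL 3 or VLDL 4 (adjusted p up to 0.105). The call of Nav2 was lost without VLDL 3 or VLDL 4 (up to 0.0577) and that of Ccr5 without Ctrl 2 or any VLDL library (up to 0.0856). The largest rises were in Tmie at 1.22 ± 0.19 (0.0021), Spsb1, a substrate receptor of ubiquitin ligases, at 1.09 ± 0.18 (0.0027), Map2, a microtubule-binding protein, at 1.05 ± 0.18 (0.00335) and Ddx43 at 1.03 ± 0.20 (0.00764). Synpo, Ddx60, Tbc1d30, Rundc3a, Cnr2, which encodes cannabinoid receptor 2, and Apol7e followed, between 0.97 and 0.82. The calls of Synpo (adjusted p up to 0.0951), Ddx60 (up to 0.202) and Rundc3a (up to 0.115) were lost without, respectively, Ctrl 3, VLDL 1 or VLDL 3; any library other than VLDL 1; and any of the 7 libraries.

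The second comparison asked whether LDL at the same concentration changed the cells. With LDL (n = 4) against Ctrl (n = 4), 0 of 11991 genes passed the edgeR quasi-likelihood test, and the smallest adjusted p was 0.887. 417 genes had an unadjusted p under 0.05, where chance gives 600; DESeq2 called 0 and limma-voom 0. With the replicate number as a block, which pairs these libraries, 876 genes had an unadjusted p under 0.05, more than the 600 that chance gives. In that blocked fit 1 gene was called, Tha1, an amino acid aldolase, at 0.77 ± 0.14 in the fit without the block. Tha1 had the smallest p in that fit too, without passing. Among genes with a mean log2 CPM of at least 2, the next smallest p of higher genes were those of Insl3 at 0.37 ± 0.08 and Tmem158 at 0.38 ± 0.10, and the smallest of lower genes those of Gdf11 at -0.35 ± 0.10 and Usp40 at -0.28 ± 0.08 (each adjusted p = 0.999).

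Of the genes named above for VLDL, 0 passed with LDL. Both comparisons share the Ctrl libraries, so genes picked for a change with VLDL lean the same way with LDL even with no effect of LDL. Tap1 was at 0.08 ± 0.05 with LDL, Zbp1 at -0.05 ± 0.07, Hmgcs1 at -0.06 ± 0.07, Fasn at -0.01 ± 0.07, Myc at 0.01 ± 0.07 and Hic1 at -0.01 ± 0.15 (edgeR adjusted p = 0.999 for each). Cdkn1a was at -0.26 ± 0.08, Ccng1 at -0.16 ± 0.06, Il5 at -0.71 ± 0.37, Lrp1 at -0.38 ± 0.18, Ikzf2 at -0.28 ± 0.13, Prr5l at -0.41 ± 0.14, Hk2 at -0.18 ± 0.06, Hspd1 at -0.12 ± 0.05 and Psat1 at -0.10 ± 0.05 (0.999 for each). The LDL and Ctrl libraries did not overlap for Prr5l, Hk2, Hspd1 and Psat1. Among all tested genes 2.63% did not overlap, where chance gives 2.86%. The interferon-gamma-induced list had a mean log2 fold change of 0.00 (camera 0.209), the type I list 0.05 (0.485) and cholesterol synthesis 0.01 (0.594). 8 of 44 lists passed camera with 0 members called in each, and 0 lists passed with an estimated correlation or with fry. The lower ones were p53 targets (camera 0.00486, and adjusted p = 0.592 with an estimated correlation), the integrated stress response (0.00486 and 0.751), MYC and ribosome biogenesis (0.00573 and 0.751), heat shock (0.0235 and 0.751), B cell markers (0.0235 and 0.804), conventional dendritic cell markers (0.024 and 0.751) and T cell activation (0.0419 and 0.751). The naive and central memory list was the higher one (0.0213 and 0.804). Their medians ran from -0.21, for the B cell markers, to 0.09. Leaving out Ctrl 4 gave 14 lists, LDL 2 14, LDL 1 5 and LDL 3 3, and the p53 list passed in each fit that left out 1 library. The others did not pass in some: the integrated stress response and ATF4 target list without Ctrl 3 (0.0662) or LDL 3 (0.194), MYC and ribosome biogenesis without Ctrl 1 (0.0881), and the heat shock response list without Ctrl 1 (0.0537), Ctrl 2 (0.0516), LDL 1 (0.0914) or LDL 3 (0.0887). B cell markers did not pass without Ctrl 1 (0.948), Ctrl 2 (0.0516), LDL 2 (0.0522), LDL 3 (0.268) or LDL 4 (0.0546), and dendritic cell markers without Ctrl 1 (0.285), LDL 2 (0.0817) or LDL 3 (0.318). The T cell activation and inhibitory receptors list did not pass without Ctrl 3 (0.197), Ctrl 4 (0.0991), LDL 1 (0.114), LDL 3 (0.219) or LDL 4 (0.0734), and the naive list without Ctrl 2 (0.567), Ctrl 3 (0.0763), LDL 1 (0.0645), LDL 3 (0.219) or LDL 4 (0.253). In the blocked fit the Th2 (0.00115), cytotoxic effector (0.00852), unfolded protein response (0.0342) and NK cell and ILC (4.01e-05) lists passed as well, each lower with LDL and with 0 members called. In the fit without the block these lists had adjusted p = 0.804, 0.804, 0.804 and 0.751 with an estimated correlation, in the same order, and 0.886 each with fry. In simulations with 4 against 4 libraries, 40% of changes of 0.32 on the log2 scale and 83.9% of 2-fold changes were found. Single changes of the median size seen with VLDL would therefore often be missed. For VLDL against Ctrl 35.5% of changes of 0.32 were found in simulations, and 1130 genes were called in the data. The simulations held no shared effect of the replicate number, by which LDL and Ctrl libraries pair, so their shares may not hold for these libraries. With the block, 1 gene was called for LDL against Ctrl and 2300 for VLDL against Ctrl. These counts of called genes argue against a response to LDL as wide and as large as that to VLDL.

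The third comparison tested the difference between both lipoproteins. With VLDL (n = 3) against LDL (n = 4), interferon-gamma-induced genes were higher in 17 of 36 cases and genes of cholesterol synthesis lower in 13 of 25. Gbp5, an interferon-induced GTPase, was higher by 0.64 ± 0.10 (edgeR adjusted p = 0.00415), Zbp1 by 0.62 ± 0.07 (0.000955), Tap1 by 0.30 ± 0.05 (0.00493) and Psmb9 by 0.35 ± 0.06 (0.00493). Scd1 was at -0.79 ± 0.10 (0.0016), Fasn at -0.58 ± 0.07 (0.00139), Hmgcs1 at -0.46 ± 0.07 (0.0046) and Myc at -0.44 ± 0.08 (0.00718). 551 genes were called, 236 higher (42.8%) and 315 lower; 537 of these had no overlap between libraries, and 18.1% of tested genes had none, where chance gives 5.71%. With upper-quartile scaling 295 were higher (52.9%) and 263 lower, and here too the direction with more genes changed with the scaling. With a B cell score as covariate 287 genes were called, 110 higher and 177 lower. The count was 350 without LDL 1, 298 without LDL 3, 214 without VLDL 3 and 233 without VLDL 4.

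In this comparison the interferon-gamma list had 27 members higher on the list alone, camera 1.08e-20, and adjusted p = 0.106 with an estimated correlation; 11 were called without LDL 1, 9 without VLDL 3 and 6 without VLDL 4. Antigen presentation had 11 of 27 higher, 20 on the list alone, camera 1.2e-13, and adjusted p = 0.106 with an estimated correlation. Its number was 7 without LDL 1, 7 without LDL 2, 5 without LDL 3, 7 without VLDL 1, 5 without VLDL 3 and 3 without VLDL 4. The type I list had 7 of 48 higher, 16 on the list alone, camera 2.72e-08, and adjusted p = 0.49 with an estimated correlation. Its number was 3 without LDL 1, 4 without LDL 2, 3 without LDL 4, 3 without VLDL 3 and 2 without VLDL 4, where the mean fell from 0.21 to 0.00. The B cell markers moved with these groups: 2 of 14 were higher, Cd19 by 0.94 ± 0.20 (0.0178) and Ms4a1 by 0.83 ± 0.21 (0.042), 6 on the list alone, with a median of 0.64, camera 2.17e-05, and adjusted p = 0.451 with an estimated correlation. 0 were called without LDL 3, VLDL 1 or VLDL 4 and 1 without LDL 2 or LDL 4; Ms4a1 was at 0.51 without VLDL 1. Conventional dendritic cell markers include MHC class II genes that are also on the antigen presentation list, among them Cd74 at 0.68 ± 0.17 (0.0349). These dendritic cell markers had 1 of 10 higher, camera 5.49e-05, and adjusted p = 0.106 with an estimated correlation. 0 of them were called without LDL 3 or VLDL 4 and 2 without LDL 4 or VLDL 3; Cd74 was lost without LDL 3, LDL 4, VLDL 1 or VLDL 4 (adjusted p up to 0.129). NF-kB targets were higher in 7 of 22 cases, 14 on the list alone, with Relb at 0.57 ± 0.09 and Nfkb2 at 0.39 ± 0.06 (0.00493 each), camera 9.98e-12, and adjusted p = 0.0336 with an estimated correlation; 3 were called without LDL 3 and 4 without VLDL 4.

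Cholesterol synthesis had 22 members lower on the list alone, camera 3.64e-19, and adjusted p = 0.14 with an estimated correlation, with 8 called without VLDL 4. Fatty acid synthesis had 8 of 20 lower, 15 on the list alone, camera 4.61e-14, and adjusted p = 0.0336 with an estimated correlation, with 5 called without VLDL 4. MYC and ribosome biogenesis had 11 of 30 lower, 24 on the list alone, camera 9.64e-16, and adjusted p = 0.0336 with an estimated correlation. The number was 7 without LDL 1, 7 without LDL 3, 5 without VLDL 3 and 6 without VLDL 4. The polymerase I subunit Polr1b was at -0.42 ± 0.07 (edgeR adjusted p = 0.00582) and Srm, spermidine synthase, at -0.34 ± 0.06 (0.00678). Hypoxia targets had 9 of 22 lower, camera 9.67e-08, and adjusted p = 0.14 with an estimated correlation, with Ndrg1 at -0.78 ± 0.13 (0.00493) and 5 called without VLDL 3. p53 targets had 2 of 21 lower, 12 on the list alone, camera 6.18e-07, and adjusted p = 0.0336 with an estimated correlation; Cdkn1a was at -0.68 ± 0.09 (0.0016). 1 was called without LDL 1, LDL 2, LDL 3 or any VLDL library. The integrated stress response had 8 of 31 lower, camera 2.41e-05, and adjusted p = 0.344 with an estimated correlation, with 5 called without LDL 1, LDL 2 or LDL 4, 4 without LDL 3 and 1 without VLDL 3 or VLDL 4. In this comparison 551 of 11991 genes were called, and 2496 had an unadjusted p under 0.05. G1/S and replication had 0 of 34 called, 5 higher on the list alone, camera 2.17e-05, and adjusted p = 0.548 with an estimated correlation. Without VLDL 4, 2 of its members were called. Among genes with a mean log2 CPM of at least 2 and no overlap, the largest changes were Hic1 at -1.93 ± 0.18 (0.000176), Gcnt2 at -1.76 ± 0.32 (0.00822), Nav2 at -1.60 ± 0.29 (0.00822), Hbegf, a ligand of the EGF receptor, at -1.32 ± 0.12 (0.000176), and, higher, Lad1 at 1.44 ± 0.29 (0.0147), Bcl11a at 1.13 ± 0.29 (0.0397), Spsb1 at 1.12 ± 0.17 (0.00437) and Map2 at 1.01 ± 0.17 (0.00534). Bcl11a was at 0.71 without VLDL 1; its call was lost then and without LDL 2, LDL 3, LDL 4 or VLDL 3 (adjusted p up to 0.179), and that of Lad1 without VLDL 1 or VLDL 3 (up to 0.0557).

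Of the interferon genes and receptors, 1 of 8 was higher with VLDL than with LDL, Jak2, at 0.43 ± 0.07 (edgeR adjusted p = 0.00582), camera 0.00169, and adjusted p = 0.106 with an estimated correlation; 2 were called without LDL 3. The naive and central memory T cell list had 3 of 22 higher, with Als2cl at 0.49 ± 0.07 (0.00342), camera 0.00189, and adjusted p = 0.49 with an estimated correlation; camera did not pass without LDL 2 (0.101), and 1 was called without VLDL 3. The lipoprotein receptors and lipid handling list had 4 of 26 lower and 1 higher, with Soat1 at -0.47 ± 0.08 (0.00493) and Lrp12 at -0.51 ± 0.09 (0.0076), camera 0.0278, and adjusted p = 0.14 with an estimated correlation. Camera did not pass for it without LDL 2 (0.125), and the higher member was lost without any library other than LDL 2. The cytosolic ribosomal proteins had a median of -0.06 with 0 of 57 called, 0 also adjusted over the list alone, camera 0.00304, and adjusted p = 0.705 with an estimated correlation; camera did not pass without LDL 2 (0.0565) or VLDL 4 (0.43).

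Both comparisons with Ctrl share its 4 libraries, so their fold changes correlate even with no effect. Over 11991 genes, which are not independent replicates, log2 fold changes with LDL and with VLDL correlated at r = 0.401, where 50 simulations of unchanged groups against shared controls gave a mean of 0.492 (0.468 to 0.521). The covariance was 0.0176 against a simulated mean of 0.015 (0.0138 to 0.0168). Among libraries numbered 1, 3 and 4 it was 0.0206, with fewer shared controls than simulated, so that range does not apply to it. The simulations modelled neither shared numbers nor an effect of VLDL alone, which would also move r. 66.4% of genes had the same sign, against a simulated 66.2%. When the controls were split into 2 and 2 over 6 assignments, r had a mean of 0.00959 (-0.0831 to 0.101) and the covariance a mean of 0.000442. 0 genes were called in both comparisons, where independent lists give 0 since LDL called 0.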

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

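The check for samples far from the others was applied to the genes named in the text, which were in part chosen after the values were seen. The tests with a B cell score, a correction for GC content and length, the numbers 1, 3 and 4 alone and thinned counts, and those on dividing cells and sterol loading, were chosen after the results were seen.

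In 17 of 276 sets of 4 libraries, 1 library lay far from the other 3, where chance gives about 1 in 20; 10 of the 17 were in the 2 libraries numbered 2. In Ctrl 2, Ahnak was at 397 CPM (others 155 to 176), Ifng at 11.7 CPM (2.97 to 3.95) and Spsb1 at 24.8 CPM (16.8 to 17.4). In LDL 2, Ifng was at 12.1 CPM (2.51 to 3.57), Gzma at 95.8 CPM (13.4 to 23.4), Gzmb at 1692 CPM (690 to 846), Irf4 at 230 CPM (163 to 172), Emilin2 at 44.2 CPM (25.3 to 27.5), Car5b at 14.8 CPM (7.78 to 8.98) and Fdft1 at 222 CPM (238 to 240). Elsewhere, Atf4 was at 311 CPM in Ctrl 1 (359 to 362), Ms4a1 at 56.6 CPM in Ctrl 1 (34.9 to 38.2), Hk2 at 155 CPM in Ctrl 3 (133 to 136), Egln3 at 226 CPM in LDL 3 (256 to 259), Hmgcs1 at 1159 CPM in LDL 3 (1011 to 1035), Gbp5 at 43.5 CPM in LDL 4 (51.2 to 52.8) and Ldlr at 510 CPM in LDL 4 (452 to 457).

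Interferon-gamma-induced genes were higher with VLDL by a mean log2 fold change of 0.27. With a B cell score as covariate the mean was 0.24 and 17 members were called in place of 20. The mean log2(CPM + 1) of the B cell markers was 3.779 ± 0.362 in Ctrl and 4.093 ± 0.392 with VLDL (SD), with overlapping libraries. An imprecise score corrects only in part, so more B cells in the VLDL cultures are not excluded. A correction for GC content and transcript length gave 0.276 with 21 called. Since no VLDL library carries the number 2, the libraries numbered 1, 3 and 4 were compared alone, which gave 0.305 with 21 of 35 called. A response of the T cells to VLDL could give this pattern, but cell types other than B cells were not modelled.

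MYC target and ribosome biogenesis genes were lower with VLDL. Correction for GC content and length gave a mean of -0.216 with 18 called, so that bias does not account for most of the fall. Thinning the counts to the smallest library gave -0.223 with 21 called. Thinning keeps each gene's expected share of a library, so it could not decide whether depth plays a part. Fewer dividing cells would lower replication genes. The mean of that list was 0.111 (SE 0.0141 over members), with 0.0357 (SE 0.018) for mitosis genes, the opposite direction. Members of a list are not independent, and VLDL and Ctrl libraries overlapped in the means of both lists (unadjusted exact permutation p = 0.114 each). A fall of these lists was not seen, but their rise is not established over libraries.

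Cholesterol synthesis genes were lower with VLDL, and correction for GC content and length gave a mean of -0.236 with 14 called. Loading of the cells with sterol would be likely to raise LXR targets as well. The mean of their list, which also holds Nr1h2, was -0.0393 (SE 0.0779, 11 members). Sterol loading and its absence therefore cannot be told apart with these data.

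Each comparison was also run on the other ways to divide the same libraries into groups of the same sizes, 35 in all with the real one. For VLDL against Ctrl, 1 of 35 gave as many genes, the real one with 1130, and the highest other had 387, with Ctrl 2, Ctrl 3 and Ctrl 4 against the rest. For VLDL against LDL it was 1 of 35, with 551 and 85. For LDL against Ctrl the real count was 0, which each of the 35 reaches by construction, so this count says nothing about chance; the highest other had 51. For gene lists passing camera, 5 of 35 gave at least the real 21 for VLDL against Ctrl (highest other 25), 26 of 35 at least 8 for LDL against Ctrl (highest other 21), and 8 of 35 at least 18 for VLDL against LDL (highest other 20), so chance is not excluded for the counts of lists. For LDL against Ctrl, whose libraries pair by number, the 8 divisions that part every pair gave 0 genes and up to 11 lists, and dividing the numbers 1 and 2 from 3 and 4 gave 18 genes and 21 lists.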

How the results depend on the processing

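The tests with a correction for GC content and length, a B cell score, summed isoforms and thinned counts were chosen after the results were seen. With the replicate number as a block, 2300 genes were called for VLDL against Ctrl, 1 for LDL against Ctrl and 1774 for VLDL against LDL, and 2393, 2 and 1957 with the block and a correction for GC content and length. LDL and Ctrl libraries pair by number, and the block changed no LDL against Ctrl call beyond Tha1 and the 4 lists named with that comparison. VLDL libraries share numbers with the others (r 0.0866 to 0.289 with Ctrl and 0.0645 to 0.294 with LDL), and 10 of 11 libraries correlated best with their own number, a hint from the data and not the design. Under the block Ifng turned to 0.58 (adjusted p = 0.0461) for VLDL against Ctrl and 0.65 (0.0289) for VLDL against LDL, and to 0.58 (0.0436) and 0.65 (0.0261) with the correction as well; the block compares VLDL within numbers 1, 3 and 4, so the high values of the libraries numbered 2 no longer enter. A B cell score as covariate gave 287 genes for VLDL against LDL and 14 lists for LDL against Ctrl; the cause was not tested. With 1 library left out, called genes ran from 440 to 1177 for VLDL against Ctrl, were 0 for LDL against Ctrl and ran from 214 to 524 for VLDL against LDL; lists for LDL against Ctrl ran from 3 to 14. With an estimated correlation 2, 0 and 4 lists passed in the order VLDL against Ctrl, LDL against Ctrl and VLDL against LDL, and with fry 13, 0 and 11; both allow for correlation between genes. The correlation of LDL and VLDL responses was 0.00959 with the controls split 2 and 2 and 0.354 with the block. Their covariance with the block was 0.0156. No simulation was run with the block, so the simulated range of 0.0138 to 0.0168 does not apply to it. Foxp3 passed for VLDL against Ctrl with the block (-0.80, adjusted p = 2.75e-05), and with the block and the correction (-0.81, 3.28e-06). Named genes were not followed under upper-quartile scaling, the low-count filter on CPM, fits of the compared groups alone, limma-voom or separate transcripts. Under the other alternatives, 160 of 442 log2 fold changes of named genes, 197 of the 442 called, changed sides of the threshold or reversed. Those that reversed were the 2 of Ifng, under both settings with the block. DESeq2 left 420 of the 442 on their side of the threshold and brought 21 past it, library-size scaling left 432, summing isoforms lost 18, thinning lost 19 and the B cell covariate lost 53. Depth limits the calls: with counts thinned to the smallest library 967 genes were called for VLDL against Ctrl and 459 for VLDL against LDL.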

Other observations

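Targets of IL-2 and STAT5, the signal added to these cultures, moved both ways with VLDL against Ctrl: 7 of 26 were higher and 4 lower, 8 and 7 adjusted over the list alone. Socs1 was at 0.36 ± 0.05 and Tnfrsf18 at 0.33 ± 0.06, while Ikzf2 was at -0.82 ± 0.14 and Myc at -0.43 ± 0.08 (edgeR adjusted p = 0.0018, 0.00343, 0.00372 and 0.00539). Camera, which tests for 1 direction, gave the list 0.315, and the mixed test of fry 4.67e-09. Without VLDL 3, 4 were higher. The mixed test passed for most lists in this comparison, so passing it is not particular to the lists named here. Oxidative phosphorylation (0.0103) and fatty acid oxidation (0.000136) passed it as well, while Th2 (0.109) did not. Regulators of apoptosis were higher in 3 and lower in 4 of 29 cases (camera 0.715, fry mixed 3.04e-05), with the survival gene Mcl1 at 0.37 ± 0.07 (0.00526) and the death gene Bbc3, a p53 target, at -0.73 ± 0.16 (0.0125), whose call was lost without VLDL 4 (0.0542). The number lower was 2 without Ctrl 3, 1 without VLDL 3 and 0 without VLDL 4. Of the TGF-beta targets 2 of 16 were higher (camera 0.364), among them the inhibitory gene Smad7 at 0.61 ± 0.09 (0.00163); 1 was called without Ctrl 2, Ctrl 3, VLDL 3 or VLDL 4.

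Immediate early genes were higher in 2 and lower in 4 of 23 cases (camera 0.846, fry mixed 0.000105), with 2 lower without Ctrl 3, Ctrl 4, VLDL 1 or VLDL 3. The unfolded protein response had 5 of 24 lower and 1 higher (camera 0.0424, and adjusted p = 0.705 with an estimated correlation); camera did not pass without Ctrl 2 (0.115), Ctrl 3 (0.0761), Ctrl 4 (0.1) or VLDL 1 (0.113), and the number lower was 1 without any of these 4 and 0 without VLDL 3 or VLDL 4. Histone genes had 2 of 20 higher (camera 0.0319, and adjusted p = 0.35 with an estimated correlation); camera did not pass without Ctrl 4 (0.0743) or VLDL 1 (0.143), and 1 was called without VLDL 3. In VLDL against LDL, glycolysis genes were lower in 5 of 24 cases (camera 0.016, and adjusted p = 0.597 with an estimated correlation), with 3 lower and camera at 0.0564 without VLDL 4.

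In per-library list means, VLDL libraries lay on 1 side of every Ctrl library for 12 of 44 lists and of every LDL library for 13 of 44, and LDL of Ctrl for 0. The smallest exact permutation p over the 44 lists was 0.0571 in each comparison. That is the lowest that 3 against 4 libraries can give, while LDL against Ctrl, with 4 against 4, could have gone lower. Adjusted by Benjamini-Hochberg the smallest were 0.2094 for VLDL against Ctrl, 0.1933 for VLDL against LDL and 0.9305 for LDL against Ctrl. Over 11814 genes, which are not independent replicates, log2 fold changes correlated with GC content at a Spearman coefficient of 0.148 for VLDL against Ctrl, 0.219 for LDL against Ctrl and 0.04 for VLDL against LDL, and with transcript length at -0.128, -0.132 and -0.064.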
